A study of Rattus norvegicus with 24 samples.

How the data were processed

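Bulk RNA sequencing was performed on the medial prefrontal cortex of Sprague Dawley rats at postnatal day 45. Birth had been induced with oxytocin, and saline was the control. The labels give 24 libraries in 4 groups of 6, by sex and treatment, and the design text speaks of 6 animals per sex and treatment. Per the labels' protocols, total RNA was taken from the cortex of both hemispheres, passed a limit on RNA integrity and was selected with oligo-dT. Per the submitters' processing notes, bcl2fastq and DRAGEN were used with the rat assembly Rnor_6.0. Their versions, the annotation and the strand setting of the counting are not given in the sources used here.

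Each library has 1 deposited table of 32883 Ensembl gene IDs. Per the file headers, it holds for each gene a length, an effective length, TPM and an estimated count of reads. The estimated counts deposited by the authors need not be whole, and between 7.42% and 8.38% of the genes in a library had a count that was not. The estimated counts were rounded to whole numbers before testing, which moved a value by at most 0.5. The deposited TPM values were not used in any test, since they keep no depth.

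Groups were taken from the sample labels (title, sex and treatment), which did not contradict each other for any library. The names of the deposited files differed from them: in 24 of 24 libraries the name of the file carried the other sex and the other treatment. Libraries are therefore called labelled male or female, and labelled oxytocin or saline, throughout. If the file names were right, the comparison in labelled males would be the female comparison with its sign turned, and the comparison in labelled females would be the male comparison with its sign turned.

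The tables pair no gene ID with a name. The reference table used here (assembly GRCr8) has 47357 rows, of which 0 carry an Ensembl ID, so 0 of the 32883 IDs could be matched to a name. The 29 lists of genes fixed before the data were examined, among them cell type markers, the oxytocin and vasopressin system, stress response and sex-linked genes, could not be tested, and neither could the genes that were to be named in any case. The rule fixed beforehand took the called genes of smallest p in each direction. Without names, at most 2 higher and 2 lower IDs are printed per comparison, again those of smallest p.

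Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 14930 genes for testing and 17953 untested, 10783 of them at 0 in all libraries. Library sizes were scaled by TMM, whose factors lay between 0.971 and 1.03. A model with 1 mean per group over all 24 libraries was fitted by quasi-likelihood with robust dispersion, and its contrasts gave oxytocin against saline within each labelled sex, their average, their difference (the interaction) and labelled males against labelled females. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05 within its contrast. The design text of the series names the same limit together with a linear fold change of at least 2, so counts at that fold are given too. The biological coefficient of variation was 10.5%. Fold changes are log2 values with standard errors (SE), and levels are TMM-scaled CPM, the reads of a gene relative to the library total, as mean ± SD. Library totals and principal components (of log2 CPM with a prior count of 2, without genes called between labelled sexes) were compared by exact permutation tests, two-sided, with 6 against 6 libraries, whose smallest possible p is 0.00216.

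The libraries held 15.9 to 24.3 M estimated reads. A count of 0 allows up to 3 reads, or 0.123 to 0.189 CPM depending on the library. Intervals and floors cover counting error only. No pair of libraries within a group agreed within sampling noise, the lowest chi-square per degree of freedom being 4.92. This argues only against repeat sequencing of 1 library, not against libraries of 1 animal or litter. Every library was counted as 1 replicate, since the design text speaks of separate animals.

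The test was tested on simulated data drawn from the real means, library sizes and dispersions, with 50 genes changed at each of 4 sizes in the comparison of labelled males, over 14835 genes. It recovered 44% of the genes changed 1.25-fold, 72% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, with 6 false calls (3.87% of the calls). The changed genes were more than the real comparison called, which loosens the adjusted threshold. Counts were drawn independently around 1 mean per gene, without structure shared by libraries. These rates therefore do not give the recovery or the false share of the real comparisons.

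Alternatives listed before the data were examined were other size factors (RLE), no filter or a stricter filter on low counts, offsets from the effective lengths, the replicate number as a block, a surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma 3.58.1 with voom and sample weights, a fit of the 12 libraries of each labelled sex alone, a block for a litter shared by same-numbered animals, and leaving out each library in turn. The litter block gave the interaction and the comparison of labelled sexes only, so no treatment comparison allows for litter. Counts thinned to the total of the shallowest library were added after the data had been seen.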

Results

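Gene expression in the medial prefrontal cortex, an area of frontal cortex involved in executive control and social behaviour, was measured in rat offspring at postnatal day 45. Birth had been induced with oxytocin, the peptide hormone used to start labour, and saline was the control. The libraries fell into 4 labelled groups of 6, oxytocin and saline in males and in females. They held 19.2 ± 2.20 M estimated reads (SD, n = 24), from 15.9 to 24.3 M reads. The most abundant gene took 1.79% to 2.72% of a library, and 13740 ± 61.5 genes (SD, n = 24) reached a level of 1 CPM. In libraries labelled female, oxytocin libraries were shallower than saline libraries, at 17.4 ± 0.888 against 20.2 ± 2.18 M reads (SD, n = 6 each; exact permutation test, two-sided p = 0.00433, adjusted p = 0.00866 over 2 tests). In libraries labelled male the totals were 19.5 ± 2.31 and 19.8 ± 2.42 M reads (SD, n = 6 each; exact permutation test, two-sided p = 0.829).

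The labels were first checked with genes seen in 1 labelled sex only. ENSRNOG00000057231 had 9538 reads over the 12 libraries labelled female and 1 read over the 12 labelled male, a ratio of 9952 (95% exact interval of the counts 1786 to 393143). ENSRNOG00000060048 had 7827 reads against 1, a ratio of 8167 (1465 to 322625). In all, 4 genes were at 1 or fewer reads in every library labelled male and at 100 to 995 reads in every library labelled female. In the other direction 1 gene was found, ENSRNOG00000051257, with 4141 reads over the libraries labelled male and 14 over those labelled female, a ratio of 283 (169 to 519). In these genes all 24 libraries stood with the others of their labelled sex, which the rule that picked the genes requires. The names of the deposited files give the other sex and the other treatment for 24 of 24 libraries, and the gene IDs could not be matched to names that would tell which sex is which. Genes restricted to libraries labelled female outnumbered those restricted to libraries labelled male, 4 to 1. This goes with labels that give the opposite sex, a hypothesis weighed below that rests on unnamed genes.

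**Figure D1:**
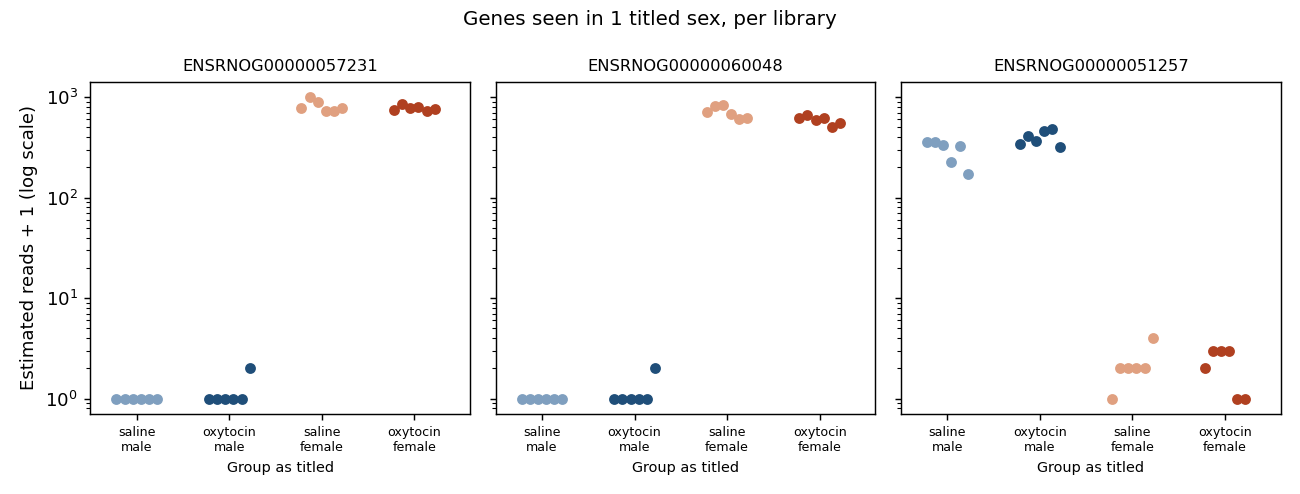
Estimated reads plus 1 (vertical axis, log scale) for 3 genes in each of the 24 libraries (points), by group as labelled. The left and middle genes had 1 or fewer reads in each library labelled male, and the right gene had 3 or fewer reads in each library labelled female.

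Between the labelled sexes, averaged over treatment, 34 of 14930 genes were called, 20 higher and 14 lower in libraries labelled male. Of these, 10 differed at least 2-fold, 2 of them higher and 8 lower in libraries labelled male. Among the 24 called genes with a smaller difference, 18 were higher in libraries labelled male. ENSRNOG00000060793 was the clearest of these. It stood at 112 ± 4.42 CPM in oxytocin and 119 ± 3.72 CPM in saline libraries labelled male, against 75.0 ± 3.11 and 77.4 ± 3.07 CPM in those labelled female (SD, n = 6 each). Its log2 fold change was 0.60 (SE 0.03, adjusted p = 1.49e-15). The labelled sexes did not overlap for 13 of the 34 genes, which had been selected for this difference, and for 0.0871% of all tested genes (7.40e-05% by chance). By the file names all these directions would be turned. DESeq2 called 109 genes and limma with sample weights 69, and 60 were called without saline female 6.

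The question of the series was whether induction with oxytocin changed expression in either sex. The labels name no litter, so animals of 1 litter would count as separate replicates in every treatment comparison. In libraries labelled male, 24 of 14930 genes were called between oxytocin and saline, 22 higher and 2 lower in oxytocin. ENSRNOG00000025604 rose from 8.63 ± 0.714 to 12.1 ± 0.864 CPM (SD, n = 6 each), a log2 fold change of 0.48 (SE 0.09, adjusted p = 0.0375). ENSRNOG00000014874 rose from 44.4 ± 1.79 to 52.4 ± 3.39 CPM (log2 fold change 0.24, SE 0.04, adjusted p = 0.0375). ENSRNOG00000017444 fell from 347 ± 28.8 to 288 ± 14.2 CPM (log2 fold change −0.27, SE 0.06, adjusted p = 0.0417). ENSRNOG00000019921 fell from 36.2 ± 2.51 to 29.8 ± 1.33 CPM (log2 fold change −0.28, SE 0.06, adjusted p = 0.0417). The call of ENSRNOG00000025604 ended with counts thinned to 1 library total (log2 fold change 0.45, adjusted p = 0.0636), an alternative chosen after the data had been seen. That of ENSRNOG00000019921 ended with length offsets (log2 fold change −0.28, adjusted p = 0.0676). With the replicate number as a block the calls of ENSRNOG00000017444 and ENSRNOG00000019921 both ended (adjusted p = 0.0674 each), with log2 fold changes still at −0.27 and −0.28. For each of these 4 genes every oxytocin library lay on 1 side of every saline library, as it did for 17 of the 24 called genes. This was so for 1.19% of all tested genes, chance gives 0.216%, and the called genes had been selected for a difference between these groups. The changes were small. Their median size was 0.33 on the log2 scale, 20 of the 24 were under 1.5-fold, and 2 genes, both higher, reached 2-fold. With length offsets 1 higher and 1 lower gene reached 2-fold, 1 of them among these 2, and without a filter on low counts 0 did. With the replicate number as a block 1 gene did, not among these 2. Leaving out each library in turn gave 0 to 10 genes at 2-fold. At an unadjusted p under 0.05 there were 1679 genes (11.2%), against 746.5 if nothing differed. Named by the files, this would be the female comparison, with saline higher where oxytocin is written.

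The count in labelled males depended on which libraries were fitted. It was 0 without saline male 1, 2, 3, 5 or 6 or oxytocin male 1, 3 or 4, 6 without oxytocin male 2 or 6, 11 without oxytocin female 3, 105 without saline male 4 and 106 without saline female 2. DESeq2 called 169 genes, limma with sample weights 121, a fit with a surrogate variable 71 and the 12 libraries labelled male alone 116. The fit with the replicate number as a block called 9, all higher.

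In libraries labelled female, 1 gene was called. ENSRNOG00000018414 fell from 89.9 ± 6.28 CPM in saline to 66.9 ± 7.21 CPM in oxytocin (SD, n = 6 each), a log2 fold change of −0.43 (SE 0.06, adjusted p = 0.00297), and all 6 oxytocin libraries lay below all 6 saline libraries. No gene reached 2-fold among the calls, so the count at that fold was 0, in DESeq2 as well, while the fit with a surrogate variable gave 1. There were 1856 genes at an unadjusted p under 0.05 (12.4%), against 746.5 if nothing differed. The call ended when the 12 libraries labelled female were fitted alone, with the log2 fold change still at −0.43 (adjusted p = 0.0886, the highest of its alternatives), and DESeq2 called 42 genes in this comparison. Left-out libraries raised the count to 6 without saline female 6, 4 without saline female 2 and 2 without oxytocin female 4. Named by the files, this gene would be higher after oxytocin in males.

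**Figure D2:**
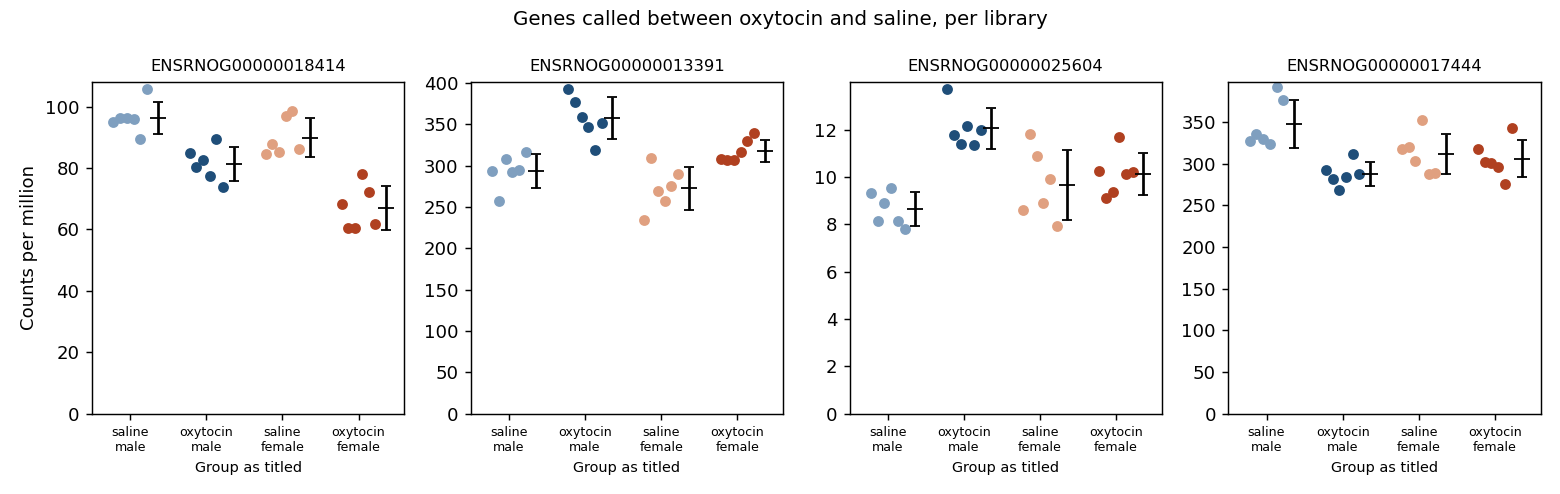
CPM (vertical axis) of 4 genes in each library (points), by group as labelled, with the mean and SD of the 6 libraries of a group (black). ENSRNOG00000018414 was lower in oxytocin in both labelled sexes, passing the test in labelled females. ENSRNOG00000013391 was higher in oxytocin in both and passed it in labelled males, as did the right pair of genes.

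Whether the sexes responded alike was tested with the interaction. No gene was called in the main edgeR fit (0 genes, smallest adjusted p = 0.426), with 1089 genes at an unadjusted p under 0.05. DESeq2 called 1, and so did the fit with the replicate number as a block. The 4 genes printed for labelled males had log2 fold changes between −0.03 and 0.06 in labelled females, and their interaction had an adjusted p of 0.532. ENSRNOG00000018414 had a log2 fold change of −0.24 (SE 0.06, adjusted p = 0.0955) in labelled males, and its interaction had an adjusted p of 0.662. A call in 1 labelled sex is thus not shown to differ from the other. The called lists shared 0 genes, and DESeq2's lists shared 2. At an unadjusted p of at most 0.01 in both labelled sexes, 20 genes were higher in oxytocin in both, against 6.28 for independent lists (Fisher's exact test, one-sided p = 5.28e-06), 12 were lower in both, against 3.87 (p = 0.000529), and 0 went opposite ways. Genes are not independent of each other, so these p-values are too small. Across genes the fold changes of the labelled sexes, which share no library, correlated weakly (Pearson r = 0.121, Spearman rho = 0.196, covariance 0.00542).

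Averaged over the labelled sexes, 54 genes were called, 36 higher and 18 lower in oxytocin, and all 54 had 1 sign in both labelled sexes, which selection on the average favours. Oxytocin and saline libraries overlapped in each of them (0 of 54 without overlap). Of the 54, 10 were also called in the comparison of labelled males and 1 in that of labelled females. ENSRNOG00000013391 was at 358 ± 25.5 CPM in oxytocin and 294 ± 20.4 CPM in saline libraries labelled male, and at 318 ± 13.7 and 272 ± 25.8 CPM in those labelled female (log2 fold change 0.25, SE 0.04, adjusted p = 0.00694). ENSRNOG00000025527 was higher by 0.24 on the log2 scale (SE 0.04, adjusted p = 0.00694). ENSRNOG00000013391 and ENSRNOG00000025527 were also called in the edgeR comparison of labelled males (log2 fold changes 0.28 and 0.29, adjusted p = 0.0397 and 0.0379). In labelled females they were not called, with log2 fold changes of 0.22 and 0.20. ENSRNOG00000018414 was lower, with a log2 fold change of −0.34 (SE 0.04, adjusted p = 0.000409), and so was ENSRNOG00000018509, at −0.37 (SE 0.07, adjusted p = 0.0232). Of the 54 genes, 48 were under 1.5-fold. The 2 genes at 2-fold or more each had 3 or fewer reads in at least 3 libraries and 30 or more in at least 3. The libraries at 3 or fewer reads were 0 of 12 oxytocin and 4 of 12 saline libraries for 1 of these genes, and 2 of 12 and 7 of 12 for the other. The count ranged from 9 without saline male 2 to 334 without saline female 2, and was 357 in DESeq2, 211 in limma with sample weights and 116 with a surrogate variable. The split also moved, to 201 higher and 156 lower in DESeq2, 39 and 29 with length offsets, 64 and 58 without oxytocin male 5, 18 and 18 without oxytocin female 4, and 8 and 9 without oxytocin male 1. By the file names every direction in this comparison would be turned.

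**Figure D3:**
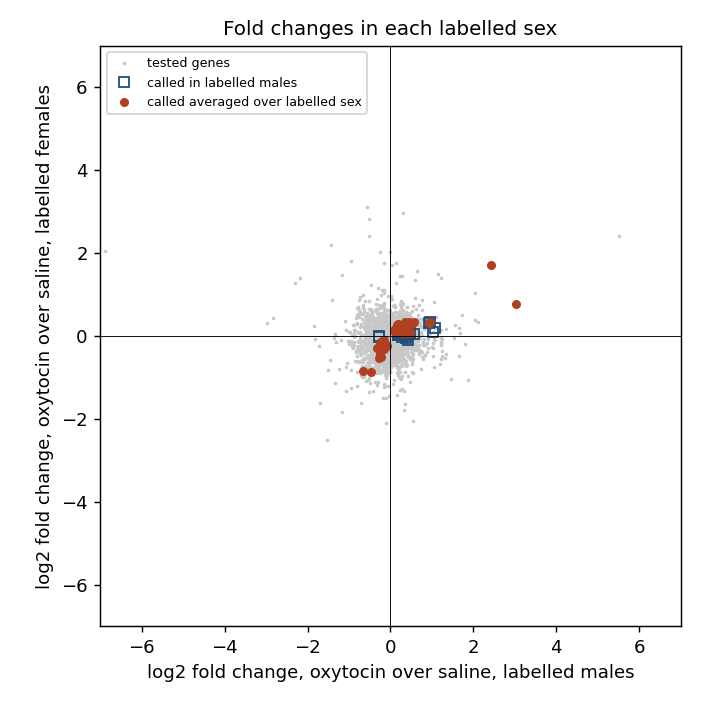
Log2 fold change of oxytocin over saline in labelled males (horizontal) and labelled females (vertical) for the 14930 tested genes (grey points). The 24 genes called in labelled males (open squares) and the 54 called on average (filled circles) are marked. Of the 24, 21 had the same sign in labelled females, with a median log2 fold change of 0.06 there (in the direction of labelled males) against 0.33 in labelled males.

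Without the genes called between the labelled sexes, the mean of the first principal component differed between oxytocin and saline in labelled males, with overlapping libraries (means −1.17 ± 6.70 and −10.3 ± 5.27, SD, n = 6 each; exact permutation test, two-sided p = 0.0195, adjusted p = 0.0390 over 4 tests). The mean of the second differed in labelled females, again with overlapping libraries (means −10.3 ± 10.6 and 8.47 ± 9.62, SD, n = 6 each; exact permutation test, p = 0.00866, adjusted p = 0.0346). The other pairings had an adjusted p of 0.652. These components held only 8.46% and 7.86% of the variance.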

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

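The tests of the labelled sex and of library size, thinning included, were chosen after the values had been seen. In 3 of 58 sets of 6 libraries, 1 library lay far from the other 5. A further 3 sets past the limit, all at 3 or fewer reads, were left out of this count but kept among the 58. Chance gives about 2.9 of 58, which covers the sets left out as well, so it is no match for the 3 listed. For ENSRNOG00000025604 oxytocin male 1 stood at 13.7 CPM, the next at 12.2. For ENSRNOG00000019921 oxytocin female 5 stood at 29.3 CPM, the next at 31.9. For ENSRNOG00000060793 oxytocin female 3 stood at 81.1 CPM, the next at 75.2.

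The labels and the file names differ on sex and treatment in every library. Male rats carry a Y chromosome whose expressed genes females lack, while few genes are silent in every male, so more genes should be restricted to males than to females. Here 4 genes were restricted to libraries labelled female and 1 to those labelled male. This goes with labels that give the opposite sex, a hypothesis that rests on unnamed genes. Of the 24 smaller differences, 18 were higher in libraries labelled male, but no outcome had been set for them. The split of all called genes, 20 higher and 14 lower, moved to 30 and 19 without saline female 5 and to 15 and 19 without saline male 1. The smaller differences were therefore not counted as support. Swaps of single libraries between the labelled sexes are argued against, since 0 libraries lay nearer to the other labelled sex over 10 genes. Those genes were picked in these same libraries for a difference between the labelled sexes. Swaps of treatment within a labelled sex were not tested. The file names are the titles in reverse order in 24 of 24 libraries, so if a single reversal of the list made the conflict, the genes above would bear on the treatment as well, but without that assumption turned treatment labels cannot be told apart from correct ones, since no gene here is known to follow the treatment.

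The labelled sexes shared a direction in 32 genes at an unadjusted p of at most 0.01. Of 80 splits (treatment labels redrawn within each labelled sex) 1, the real one, reached 32, and the highest other reached 25. Chance is thus unlikely, but this number of splits does not exclude it. Library size is argued against, since the totals differed by −0.302 M reads in labelled males, under the SD of 2.20 M reads, though by −2.79 M reads in labelled females, and since 30 genes shared a direction when all libraries were thinned to 1 total. A trend of fold change with gene length gave, at these genes, 3.50% of the median fold change in labelled males and 10.3% in labelled females, in a test also chosen afterwards. These genes were picked for a low p in both labelled sexes, which favours fold changes far above the trend. A small share was thus likely whatever the cause, and this test could not decide. In a test fixed beforehand the rank correlation of the fold changes did not stay above every other split once the trend was removed (0.185, another split 0.196), the outcome set for the trend, but the uncorrected value of 0.196 was also passed by another split at 0.207, so that test could not decide. A shared response to the treatment stays open, as do a gene length trend and differences between litters or batches that the labels do not give.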

How the results depend on the processing

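The thinning of counts was chosen after the data had been seen; all other alternatives were listed beforehand. The counts of called genes moved little with RLE size factors, a stricter filter, length offsets or thinned counts (for labelled males 23, 23, 21 and 21 against 24), though with length offsets the split became 17 higher and 4 lower, and at 2-fold 1 higher and 1 lower. They moved more under the following. DESeq2, with its own size factors and filter, called 169 genes in labelled males (5 at 2-fold), 42 in labelled females, 357 on average, 1 in the interaction and 109 between labelled sexes, with 2 shared between the labelled sexes. limma with sample weights called 121, 211 and 69 in labelled males, on average and between labelled sexes. A surrogate variable gave 71 (4 at 2-fold), 2 (1 at 2-fold) and 116 in labelled males, labelled females and on average. The 12 libraries of a labelled sex alone gave 116 (5 at 2-fold) in males and 0 in females. Without a filter on low counts 0 genes reached 2-fold in labelled males. The shared count was 32 at an unadjusted p of at most 0.01, and 30 with thinned counts. The cause of these shifts was not tested.

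By the limit set beforehand (every pair over 0.1) the replicate numbers do not pair the libraries: correlations of same-numbered libraries lay between −0.07 and 0.18. Among oxytocin and saline libraries labelled female, however, 4 of 6 correlated best with their own number and 2 pairs were over 0.1; among those labelled male 0 of 6 and 0 pairs. With the replicate block, 9 genes were called in labelled males, all higher (1 at 2-fold, not among the 2 reported), ENSRNOG00000017444 and ENSRNOG00000019921 no longer among them (adjusted p = 0.0674 each) with log2 fold changes still at −0.27 and −0.28, 1 in the interaction and 57 on average, and no other count moved by over 1.5 times.

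Leaving out each of the 24 libraries gave 0 to 106 genes in labelled males (0 to 10 at 2-fold), 1 to 6 in labelled females (0 at 2-fold in each), 9 to 334 on average, 0 in the interaction and 29 to 60 between labelled sexes. On average it gave 334, 142, 122 and 106 without saline female 2, saline female 6, oxytocin male 5 and saline male 4, 9, 12 and 30 without saline male 2, 1 and 3, 15, 17, 23 and 29 without oxytocin male 4, 1, 3 and 2, 20, 20, 24 and 33 without saline female 3, 5, 4 and 1, and 12, 21 and 22 without oxytocin female 5, 3 and 6. No printed gene changed sign in any fit. The 4 printed for labelled males stayed called in 15, 14, 10 and 8 of the 24 fits, and ENSRNOG00000018414 in 24 of 24 in labelled females and on average. The planned tests of gene lists were not run, since no ID could be matched to a name. Depth limits which low genes can be tested; thinning to 15855700 reads per library gave 53 calls on average, 42 of them among the 54.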

Other observations

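The splits of the libraries and the test of counts that are not whole were fixed before their outcome was seen; the genes near 0 in some libraries, the relation to gene length and the 9 genes that varied together were noticed in the data first. Other splits of the 24 libraries, 80 with the real one, were fitted in the same way. For labelled males 2 of 80 gave 24 or more genes, the highest other 57, so chance is unlikely but not excluded. For genes at 2-fold 1 of 80 gave 2 and the highest other gave 1, a margin too small to exclude chance. On average 1 of 80 reached 54, the highest other 26, so chance is unlikely there too. The split tests were not corrected for their number. For labelled females 6 of 80 gave 1 or more, the highest other 20, so chance cannot be excluded. At 2-fold in labelled females and for the interaction the real count was 0, which all 80 of 80 splits must reach (highest other 1 and 5), so the splits say nothing of chance there. Between labelled sexes 2 of 80 gave 34 or more, the highest other 120, so for this count chance is unlikely but not excluded. Splits that called 20, 57 and 120 genes, well above the real counts, may reflect a structure of the libraries other than the labels; which libraries they grouped was not examined.

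Of the 14930 tested genes, 93 were near 0 (3 or fewer reads) in at least 3 libraries and well expressed (30 or more) in at least 3, leaving out genes called between labelled sexes, and 92 of the 93 showed both states within a group. Counts that were not whole (by over 0.001) in at least 1 library were found in 95.7% of them, against 21.0% of 5683 other tested genes of the same range of abundance (Fisher's exact test, one-sided p = 6.55e-54, odds ratio 83.7). Reads shared between near-identical genes are a candidate explanation. Variants carried by some of these outbred animals stay open and could not be tested, since 0 IDs were matched to positions. Both genes called on average at 2-fold or more met these read limits, their libraries near 0 being mostly saline, and 1 of them had counts that were not whole; of the 2 such calls in labelled males, 0 were.

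In labelled females the fold change rose with gene length across genes (Spearman rho = 0.20), from a median of −0.04 (log2) among the shortest 20% of genes to 0.04 among the longest 20%; in labelled males rho was 0.06. Of 80 splits 7 gave a rho as large and above 0 in labelled females, the highest other 0.30. Splits as far below 0, where rho reached −0.30, were not counted, though a redrawn split has no set direction. Chance thus cannot be excluded.

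A set of 9 abundant genes varied together across the libraries of a group. After group means were removed, they had a correlation of at least 0.8 with the most variable gene of 3152 above a mean log2 CPM of 6. Their mean log2 level relative to all libraries ran from −0.91 in oxytocin male 3 to 0.69 in oxytocin female 6, with −0.80 in saline male 4 and −0.66 in oxytocin female 4. It did not follow the treatment labels past the threshold (exact permutation test, two-sided adjusted p = 0.506 in labelled males and 0.372 in labelled females), and 0 of the 9 were called in any treatment comparison. The set was picked for its variation within groups (median SD 0.376 on the log2 scale, against 0.0759 for all abundant genes). That choice works against a difference between groups, so neither result speaks against a treatment effect on these genes.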
